A study of Mus musculus with 16 samples.

How the data were processed

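Small RNA was sequenced from mouse 3T9 fibroblasts, an immortalised line grown from embryo cells. Per the labels' protocols, the cells were held without serum for 72 h and then given medium with 10% fetal bovine serum. Libraries were made from 1000 ng of total RNA with the Illumina TruSeq small RNA kit after extraction with a miRNeasy kit. The 16 libraries analysed here cover 0, 1, 2, 4, 6, 8, 10 and 12 h of serum, with 2 libraries at each time, and the series design text calls the replicates independent biological experiments. A further time point named in that text was not analysed here.

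The deposited table holds raw read counts per miRNA and sequence class in 1 column per library, per the file headers, and no normalisation was applied to the counts by the authors as far as the values show. CASAVA 1.8.0 is named in the submitters' processing notes. The aligner, the miRBase release, the genome build and the rules for mismatches and for reads that match several miRNAs are not given in the sources used here. Each miRNA has separate counts for reads equal to its reference, trimmed reads, and reads extended at the 3' end or at the 5' end. Bases added at the 3' end match the hairpin (templated) or do not (sorted into A, U, C, G and mixed forms). These meanings were read from the class names. The table has 6511 entries, of which 1 was an identical duplicate and was dropped. The entries for added bases repeat the reads of the non-templated class, so summing all entries would have counted 9.55% to 10.5% of the sum more than once. Each read was therefore counted once, which gave totals for 1167 mature miRNAs. The header names 2 sequencing runs, and each run holds all libraries of 1 replicate number, so the run and the replicate number cannot be told apart.

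Libraries held 5852087 to 7783249 miRNA reads. A count of 0 in a library allows up to 0.385 to 0.513 CPM (reads scaled to a common library total), taken as 3 counts of its total. Intervals and limits of this kind cover counting error only, since the reads carry no molecular identifiers. Between 737 and 816 miRNAs were detected per library, and the 5 miRNAs with the most reads over all libraries took 50.3% to 55.2% of the reads. The replicates of a time differed by more than counting noise at every time, with chi-square values of 69.4 to 372 per degree of freedom, and no libraries were duplicates.

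The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts of each mature miRNA, with TMM scaling (factors 0.935 to 1.07), filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. The filter kept 449 miRNAs and left out 718, and in every library at least 99.986% of the reads lay on the tested miRNAs. All 16 libraries entered 1 fit, so the times shared 1 estimate of the spread (prior degrees of freedom 5.83). Fits were made for any change over the 7 later times, for each later time against 0 h, and for a linear trend of log2 expression per hour. Every adjusted p given for a single miRNA comes from this test and adjustment unless another is named. Log2 changes carry an approximate standard error (SE), taken as the size of the change over the square root of its F statistic. CPM values, computed on TMM-scaled totals, are given as mean and standard deviation (SD) over the 2 libraries of a time. A miRNA is said to have risen, fallen or changed only where its adjusted p was under 0.05.

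Lists of miRNAs were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Of 16 lists, 14 had at least 3 measured members. The lists are the miR-322/503 cluster, the miR-15/16 family, miR-17-92 with its paralogous clusters, miRNAs described as growth-factor-induced, the let-7, miR-29, miR-34 and miR-30 families, SRF-linked and muscle miRNAs, the miR-23/27/24 clusters, the Dlk1-Dio3 cluster, and markers of blood, liver and gut, neural, epithelial and pluripotent cells. A mature miRNA belonged to a list when its hairpin was in it. For hairpins with both arms measured, the log2 change of the less abundant (minor) arm minus that of the more abundant (major) arm was tested by a 2-sided sign-flip permutation test over hairpins, and the minor arms' share of reads was correlated with time by permutation, each with 100000 resamples. These tests, the lists, the rule for named miRNAs and the settings listed below, except 1, were fixed before the data were examined. Trend fits within each run and the test of whether slopes differ between runs were added later.

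The rule named the 10 largest rises and the 10 largest falls at 12 h among miRNAs past the test of any change whose 12 h minus 0 h difference had the same sign in both runs (with 0.5 CPM added). It also named the 3 largest rises and falls at 1, 2 and 4 h, the 5 most abundant miRNAs, the 4 most abundant members of each list (some of which are left out below) and 10 miRNAs set in advance, each by its more abundant arm. miRNAs outside the rule that are named below were chosen after their values were seen. Hairpin genes were matched by name to GENCODE M21 on GRCm38, and 429 of the 449 tested miRNAs had a match. Mature miRNAs encoded by more than 1 hairpin, such as miR-30c-5p, miR-29b-3p, miR-16-5p and miR-7a-5p, and those with near-identical relatives, such as the let-7 and miR-30 families, are uncertain, since the counting of shared reads is not known.

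The replicate numbers were taken to pair the libraries. For each pair of times, the deviations of same-numbered libraries from their time means were correlated across miRNAs, and all 28 correlations exceeded 0.1 (0.106 to 0.569, median 0.267). Over the 193 miRNAs with a mean log2 CPM over 5 they were higher (0.229 to 0.819, median 0.541). A second fit had the replicate number as a block (prior degrees of freedom 7.7). A difference between the runs alone would also give such correlations, so they do not show that the experiments pair. The main fit leaves this shared difference in its estimate of the spread. So do the other settings below, each run without the block. The value with the block is therefore printed beside each result that it moves across the threshold, or by more than 1.5 times for a count.

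The other settings tried were DESeq2 size factors, total counts without TMM, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, robust edgeR fits, fits of only the groups compared, a log2 scale of time, trends without the 0 h libraries, and each library left out in turn. An alternative without 10 h replicate 2 and 2 h replicate 2, the libraries with the largest residuals (root mean square 0.215 and 0.192 on the log2 scale), was chosen after seeing the data. Where 1 library of a time is left out, the other is assumed to vary like the rest. The filter was then applied anew, which let 468 to 474 miRNAs into the test. For miRNAs with 1 to 3 reads at a time, ratios of summed reads are given with an exact 95% binomial interval. Shares of reads in end classes were compared over 112 miRNAs above 200 CPM, as described in the closing part. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for these steps and the plots.

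The fits were tested on simulated counts with the real means and library sizes, in which 200 miRNAs were changed by known folds. At 12 h against 0 h, 76.1% of the 2-fold changes (51 of 67), 14.9% of the 1.5-fold changes (10 of 67) and 93.9% of the 4-fold changes (62 of 66) were called in the right direction. The simulated data were filtered again, which left 437 miRNAs tested, and changed miRNAs lost to the filter count as missed. Unchanged miRNAs made up 3.9% of those calls. For the linear trend the recovered shares were 53.7% at 1.5-fold, 95.5% at 2-fold and 98.5% at 4-fold, and 2.4% of calls were false. With no changes simulated, 1 call was made at 8 h and 0 at the other times, for any change and for the trend. The simulated log2 changes grew linearly with time, and libraries were drawn independently, without a shared difference between runs. The shares recovered for the trend therefore do not carry over to early peaks. The shares of false calls do not carry over to libraries that share a run effect.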

Results

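Quiescent mouse 3T9 fibroblasts were followed for 12 h after serum was given back, and mature miRNAs were compared with those of serum-deprived cells (0 h). The series asks how miRNAs are regulated when resting fibroblasts re-enter growth. Each of the 8 times had 2 libraries from independent experiments, with 5852087 to 7783249 miRNA reads per library. miR-22-3p had the highest mean abundance and took 12.4% to 16.8% of a library's reads. miR-143-3p, miR-99b-5p, miR-27b-3p and miR-21a-5p came next in mean abundance.

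Over the whole course 62 of 449 tested miRNAs changed. Of these, 59 had the same sign of the 12 h difference in both experiments, 33 higher and 26 lower. Both arms of miR-155, a regulator of immune responses, changed (adjusted p = 1.06e-05 for miR-155-5p and 1.23e-06 for miR-155-3p, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). miR-155-5p stood at 79.7 ± 5.04 CPM (SD, n = 2) at 0 h, 384 ± 41.9 at 4 h and 282 ± 43.9 at 12 h. miR-30c-5p was at 2312 ± 113 CPM at 0 h and 686 ± 102 at 12 h (adjusted p = 2.96e-06). miR-26a-2-3p went from 22.8 ± 1.41 CPM at 0 h through 2.93 ± 0.107 at 6 h to 6.65 ± 0.954 at 12 h (adjusted p = 5.67e-06). With the replicate number as a block 110 miRNAs changed, and all 62 were among them. The count was 101 without a low-count filter, 39 among miRNAs with a mean of at least 10 CPM and 36 without 0 h replicate 2.

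**Figure D1:**
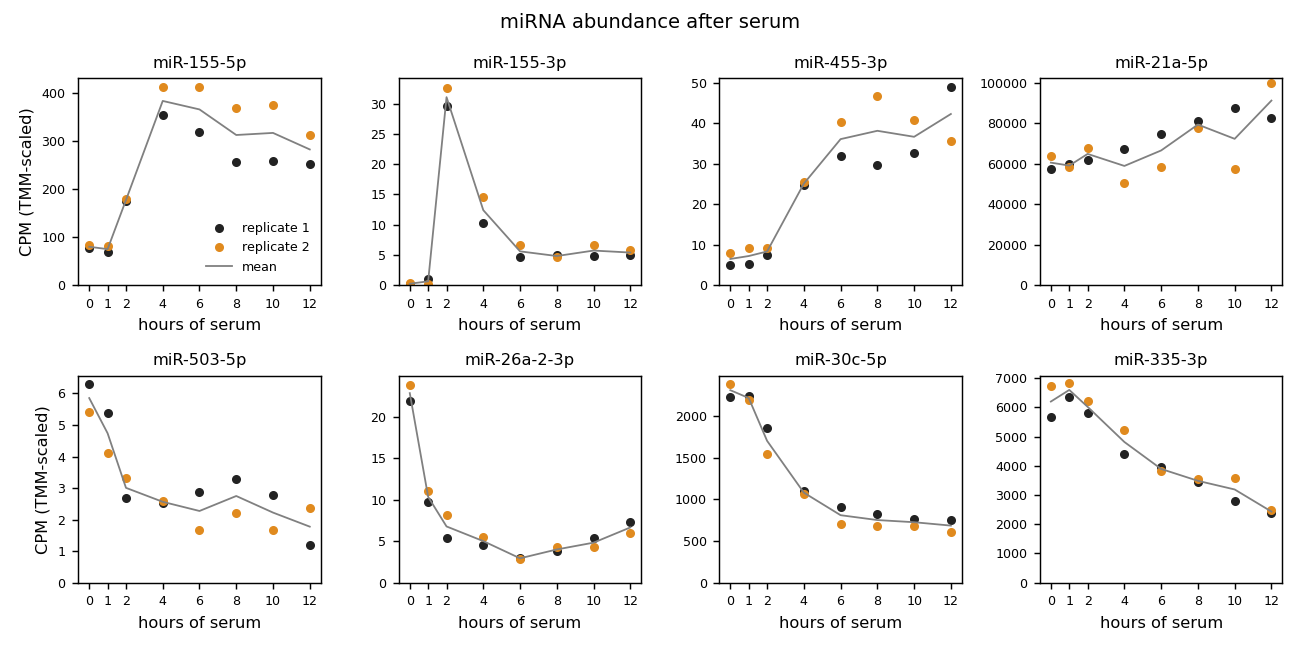
Abundance in TMM-scaled CPM (linear vertical axes, starting at 0) against hours of serum for 8 miRNAs, with 1 point per library (black, replicate 1; orange, replicate 2) and a line through the means. miR-155-3p reaches its highest mean at 2 h, miR-155-5p at 4 h, and miR-26a-2-3p its lowest mean at 6 h.

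After 1 h of serum 1 miRNA rose and 1 fell. miR-128-1-5p, from a hairpin in an intron of R3hdm1 (chromosome 1, 128202361 to 128202430, GRCm38), rose from 6.74 ± 0.231 to 17.8 ± 0.292 CPM (SD, n = 2). Its log2 change was 1.40 ± 0.23 (SE; adjusted p = 0.0134, edgeR quasi-likelihood test), and at 2 h it was at 5.97 ± 1.39 CPM. miR-26a-2-3p, from a hairpin within an annotated exon of Ctdsp2 (chromosome 10, 126995530 to 126995613), fell by 1.14 on the log2 scale (SE 0.21; adjusted p = 0.0224). Both calls were lost without either library of 0 h or 1 h (1.40 to 1.44 for miR-128-1-5p and -1.22 to -1.03 for miR-26a-2-3p), and the second also without 4 h replicate 1 (-1.11) or 6 h replicate 2 (-1.11). The count of 2 was 5 with the replicate block, 0 at a mean of at least 10 CPM, 0 without either library of 0 h or 1 h, and 1 without 4 h replicate 1 or 6 h replicate 2, while 15 miRNAs had an unadjusted p under 0.05.

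At 2 h 7 miRNAs rose and 4 fell. miR-155-3p, the less abundant arm of miR-155, rose from 3 reads in both 0 h libraries together to 425 reads, a ratio of 145 (95% interval 49.4 to 707; adjusted p = 4.4e-07, edgeR quasi-likelihood test). miR-155-5p had a log2 change of 1.15 ± 0.22 (SE; adjusted p = 0.0131). miR-29b-1-5p, the passenger arm of a hairpin of the collagen-repressing miR-29 family, rose from 6.32 ± 0.241 to 26.2 ± 3.60 CPM (log2 change 2.05 ± 0.34, adjusted p = 0.00538). miR-702-5p, whose hairpin overlaps an exon of Plod3 (chromosome 5, 136991433 to 136991541), rose by 1.86 ± 0.37 to 3.29 ± 0.0414 CPM (adjusted p = 0.0131). miR-26a-2-3p fell by 1.75 on the log2 scale (SE 0.22; adjusted p = 0.000383). miR-326-3p, from an intron of Arrb1 (chromosome 7, 99552269 to 99552363), fell by 1.32 (SE 0.27; adjusted p = 0.0134). miR-210-5p, from the hairpin of the hypoxia-responsive miR-210, fell by 0.95 (SE 0.23; adjusted p = 0.042).

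Several of the 2 h calls were lost in fits that left out 1 library. Those of miR-29b-1-5p (2.10), miR-702-5p (1.38) and miR-326-3p (-1.04) were lost without 0 h replicate 2. Those of miR-702-5p (1.88) and miR-326-3p (-1.51) were lost without 2 h replicate 2, and that of miR-326-3p also without 2 h replicate 1 (-1.01). That of miR-210-5p was lost without any single library other than the 10 h ones (-1.13 to -0.65). Fits of only the groups compared, and the fit without 10 h replicate 2 and 2 h replicate 2, ended those of miR-702-5p (1.92 and 1.88), miR-326-3p (-1.26 and -1.51) and miR-210-5p (-0.89 and -0.91). That of miR-210-5p was also lost with DESeq2 size factors (-0.91), without a low-count filter (-0.89), at a mean of at least 10 CPM (-0.90) and with limma-voom (-0.93). The count of 11 was 31 with the replicate block, 20 without a low-count filter, 6 without 0 h replicate 1, 2 without 0 h replicate 2 and 4 without 2 h replicate 2.

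At 4 h 21 miRNAs rose and 13 fell. miR-155-5p was 2.27 ± 0.23 higher on the log2 scale than at 0 h (SE; adjusted p = 2.4e-05, edgeR quasi-likelihood test). miR-155-3p had 193 reads against 3, a ratio of 58.5 (95% interval 19.7 to 286; adjusted p = 1.46e-05). miR-211-5p, encoded in an intron of Trpm1 (chromosome 7, 64205806 to 64205911), rose from 2 to 27 reads, a ratio of 12.3 (95% interval 3.09 to 107; adjusted p = 0.0324). miR-409-3p, a member of the imprinted Dlk1-Dio3 cluster, rose from 3 to 28 reads, a ratio of 8.49 (95% interval 2.62 to 43.6; adjusted p = 0.0386). miR-26a-2-3p fell by 2.19 on the log2 scale (SE 0.23) to 5.01 ± 0.646 CPM. let-7c-1-3p, a passenger arm of the let-7 family, fell by 2.07 (SE 0.58; adjusted p = 0.0443), and miR-326-3p fell by 1.54 (SE 0.27; adjusted p = 0.00206).

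The 4 h call of miR-211-5p was lost without either library of 0 h or 4 h (adjusted p 0.0516 to 0.218; range over its alternatives 0.000149 to 0.218). That of miR-409-3p was lost without these, either library of 12 h, or 8 h replicate 2 (0.0509 to 0.299; range 0.000664 to 0.299), and with the DESeq2 test. That of let-7c-1-3p was lost without either library of 0, 2, 4, 8 or 12 h (-2.49 to -1.74 on the log2 scale), with limma-voom (-2.05) and without 10 h replicate 2 and 2 h replicate 2 (-2.05). The count of 34 was 66 with the replicate block, 15 at a mean of at least 10 CPM, 18 without 0 h replicate 1, 14 without 0 h replicate 2 and 17 without 4 h replicate 2.

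At 6 h 22 miRNAs rose and 13 fell, at 8 h 28 rose and 15 fell, and at 10 h 32 rose and 21 fell. miR-26a-2-3p was at 2.93 ± 0.107 CPM (SD, n = 2) at 6 h, a fall of 2.95 on the log2 scale (SE 0.25; adjusted p = 5.5e-06, edgeR quasi-likelihood test). miR-455-3p, from an intron of the collagen gene Col27a1 (chromosome 4, 63256851 to 63256932), was above 0 h by 2.48 ± 0.32 at 6 h, 2.56 ± 0.32 at 8 h and 2.50 ± 0.32 at 10 h (adjusted p = 0.00013, 7.97e-05 and 8.99e-05). miR-335-3p, from an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), fell by 0.67, 0.83 and 0.96 at these times (SE 0.13, 0.14 and 0.14; adjusted p = 0.0072, 0.00106 and 0.000265). miR-222-3p, which represses the cell-cycle inhibitor Cdkn1b, was 0.75 ± 0.18, 1.11 ± 0.18 and 0.99 ± 0.18 above 0 h (adjusted p = 0.0187, 0.00106 and 0.00253).

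The counts of 35, 43 and 53 at 6, 8 and 10 h were 77, 81 and 84 with the replicate block. Without 0 h replicate 1 they were 17, 22 and 30, and without 0 h replicate 2 they were 16, 26 and 23. The count at 6 h was 20 without 6 h replicate 1, 16 without 6 h replicate 2 and 20 at a mean of at least 10 CPM. That at 8 h was 27 without 8 h replicate 1 and 20 without 8 h replicate 2, and that at 10 h was 29 without 10 h replicate 2. With total counts in place of TMM the median change of all miRNAs was -0.15 at 8 h, -0.16 at 10 h and -0.15 at 12 h. The split of rises and falls was then 20 and 18 at 6 h, 22 and 28 at 8 h, and 20 and 31 at 10 h.

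**Figure D2:**
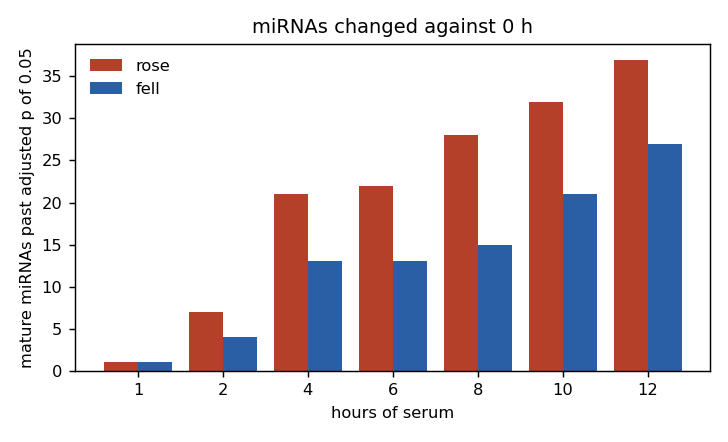
Number of mature miRNAs past an adjusted p of 0.05 (vertical axis, starting at 0) that rose (red) or fell (blue) against 0 h at each later time in hours of serum, over 449 tested miRNAs. The bars grow from 1 and 1 at 1 h to 37 and 27 at 12 h with TMM scaling. The 12 h split is 23 and 45 with total counts, and 53 and 55 with the replicate block.

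At 12 h 37 miRNAs rose and 27 fell. miR-155-3p had 70 reads against 3, a ratio of 23.3 (95% interval 7.65 to 116; adjusted p = 9.44e-05, edgeR quasi-likelihood test). miR-155-5p rose by 1.83 ± 0.23 on the log2 scale (SE; adjusted p = 7.96e-05), and their hairpin lies in an exon of the noncoding host gene Mir155hg (chromosome 16, 84714140 to 84714204). Both arms of miR-455, which is known from cartilage formation, rose. miR-455-3p went from 6.44 ± 2.18 to 42.3 ± 9.33 CPM (SD, n = 2; log2 change 2.71 ± 0.32, adjusted p = 4.61e-05) and miR-455-5p from 8.40 ± 0.586 to 37.6 ± 13.0 CPM (2.16 ± 0.31, adjusted p = 0.000287). miR-92a-1-5p, the passenger arm of a hairpin in the growth-promoting miR-17-92 cluster, rose from 76.9 ± 20.9 to 399 ± 2.42 CPM (2.38 ± 0.18, adjusted p = 1.52e-06). miR-149-5p, from an intron of the proteoglycan gene Gpc1 (chromosome 1, 92850378 to 92850443), rose from 124.4 ± 20.2 to 513 ± 204 CPM (2.04 ± 0.38, adjusted p = 0.00218). Its other arm, miR-149-3p, had 9 reads against 1, a ratio of 8.98 (95% interval 1.25 to 394). miR-149-3p passed the test of any change (adjusted p = 0.0184) but not that of 12 h (adjusted p = 0.0736, 0.0298 with the replicate block, range over its alternatives 0.0214 to 0.348).

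miR-6539, from an intron of Dock5 (chromosome 14, 67859636 to 67859745), rose at 12 h by 1.96 ± 0.27 on the log2 scale (SE; adjusted p = 0.000202, edgeR quasi-likelihood test). miR-702-5p rose by 2.02 ± 0.36 (adjusted p = 0.00165). miR-5121 rose by 2.28 ± 0.45 (adjusted p = 0.00365), a call lost without 12 h replicate 2 (1.69). Its hairpin overlaps exons of the ribosomal protein gene Rpl13a and the small nucleolar RNA gene Snord33 (chromosome 7, 45126918 to 45126991). Reads from these genes, or from Plod3 for miR-702-5p, were not told apart from miRNA reads. Among miRNAs with a matched hairpin, 12 of 61 called at 12 h overlapped an exon of a coding gene, against 56 of 429 tested. miR-22-3p rose from 129816 ± 7448 to 164428 ± 8925 CPM (SD, n = 2; 0.34 ± 0.08, adjusted p = 0.00813). miR-21a-5p, which represses the tumour suppressor Pdcd4, rose from 60505 ± 4553 to 91177 ± 12016 CPM (0.59 ± 0.18, adjusted p = 0.0434). With total counts both missed the threshold (0.18 for miR-22-3p and 0.43 for miR-21a-5p). The call of miR-22-3p was also lost without 12 h replicate 1 (0.30) or 0 h replicate 2 (0.28), and that of miR-21a-5p without either library of 0, 1 or 12 h (0.49 to 0.74). miR-143-3p, miR-99b-5p and miR-27b-3p had log2 changes of 0.19 ± 0.14, 0.13 ± 0.09 and 0.08 ± 0.09 (adjusted p = 0.421, 0.403 and 0.6), and with total counts those of miR-99b-5p and miR-27b-3p were -0.02 and -0.08.

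The miRNAs that fell at 12 h ranged from abundant to rare. miR-335-3p fell from 6197 ± 736 to 2433 ± 76.7 CPM (SD, n = 2), by 1.35 on the log2 scale (SE 0.14; adjusted p = 9.2e-06, edgeR quasi-likelihood test). miR-30c-5p, encoded by Mir30c-1 in an intron of Nfyc (chromosome 4, 120769534 to 120769622) and by Mir30c-2 (chromosome 1, 23291701 to 23291784), fell by 1.75 (SE 0.16; adjusted p = 7.31e-06). miR-26a-2-3p fell by 1.77 (SE 0.22; adjusted p = 7.96e-05). miR-351-3p (7.83 ± 0.984 to 2.89 ± 0.980 CPM) and miR-503-5p (5.85 ± 0.624 to 1.78 ± 0.822 CPM) fell by 1.43 (SE 0.25) and 1.72 (SE 0.36). Their hairpins are neighbours on chromosome X (53053255 to 53053353 for miR-351-3p and 53053984 to 53054054 for miR-503-5p). miR-652-5p fell by 2.28 (SE 0.59; adjusted p = 0.019). miR-501-5p fell by 1.45 (SE 0.31), miR-187-3p by 1.36 (SE 0.28), miR-466h-3p by 1.35 (SE 0.28) and miR-326-3p by 1.33 (SE 0.27). Calls were lost without 12 h replicate 1 for miR-503-5p (-1.28), miR-501-5p (-1.28) and miR-466h-3p (-1.18), and without 12 h replicate 2 for miR-187-3p (-1.25). They were lost without 0 h replicate 2 for miR-501-5p (-1.28), miR-187-3p (-0.98), miR-466h-3p (-1.13) and miR-326-3p (-1.06), and without either library of 0 h or 12 h for miR-652-5p (-2.52 to -2.02).

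The 64 calls at 12 h all had the same sign of change in both experiments taken singly. This is largely built in, since the calls came from a fit of both experiments together. The count was 108 with the replicate block (53 higher and 55 lower), 42 without 0 h replicate 1, 37 without 0 h replicate 2, 42 without 12 h replicate 1 and 37 without 12 h replicate 2. With total counts 68 passed, 23 higher and 45 lower. miR-29b-1-5p, which had risen at 2 h, was 1.67 ± 0.35 above 0 h on the log2 scale (SE; adjusted p = 0.00437, edgeR quasi-likelihood test). miR-128-1-5p, which had risen at 1 h, was 0.52 ± 0.24 above it (adjusted p = 0.184).

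As a linear trend over all 16 libraries, 113 miRNAs changed, 54 rising and 59 falling. miR-335-3p fell by 0.118 per hour on the log2 scale (SE 0.00811; adjusted p = 4.32e-09, edgeR quasi-likelihood test). miR-222-3p rose by 0.114 ± 0.0112 per hour (SE; adjusted p = 2.92e-07) and miR-6539 by 0.167 ± 0.0149 (adjusted p = 8.88e-08). miR-92a-1-5p rose by 0.196 ± 0.0209 (adjusted p = 8.15e-07) and miR-455-3p by 0.239 ± 0.0344 (adjusted p = 3.04e-05). miR-30c-5p fell by 0.158 per hour (SE 0.0154; adjusted p = 2.92e-07). miR-155-3p, with its highest level at 2 h, was not called over the trend (adjusted p = 0.614). All 113 trends had 1 sign in both runs, which is largely built in because both runs entered the fit. Of these, 40 were called in each run alone, where 95 and 52 miRNAs passed. No difference in slope between runs was called (0 calls in an edgeR interaction test, 24 at an unadjusted p under 0.05), which does not show that the slopes were equal. Without the 0 h libraries 59 trends passed, and with total counts 148, of which 37 rose and 111 fell.

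The list of miRNAs described as growth-factor-induced was higher than other miRNAs at 12 h. Of 18 measured members 9 rose, 0 fell and 9 were not called (11 rose adjusted over the list alone), with camera adjusted p = 4.35e-09 and adjusted p = 0.00283 with an estimated correlation. miR-155-5p was among them, as were miR-222-3p (1.30 ± 0.18, adjusted p = 0.000202, edgeR quasi-likelihood test), miR-221-5p (1.53 ± 0.15, adjusted p = 7.5e-06) and miR-212-3p of the CREB-responsive miR-212 hairpin (1.39 ± 0.28, adjusted p = 0.00365). miR-132-3p (0.73 ± 0.29), miR-212-5p (0.81 ± 0.28) and miR-221-3p (0.43 ± 0.22) had adjusted p of 0.118, 0.0668 and 0.219. With the replicate block these passed (0.0114, 0.0242 and 0.00556; ranges over their alternatives 0.0114 to 0.41, 0.0242 to 0.241 and 0.00556 to 0.608). miR-31-5p rose by 0.38 ± 0.10 (adjusted p = 0.0165), a call lost with total counts (0.23), without a low-count filter (0.40) and without 12 h replicate 1 (0.34) or 0 h replicate 2 (0.28). Over the trend 10 members rose (10 adjusted over the list alone), with adjusted p = 7.17e-07 and adjusted p = 0.0359 with an estimated correlation.

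The list of miR-17-92 with its paralogous clusters, which Myc activates, was higher at 12 h at camera's preset correlation. Of 16 measured members 4 rose and 0 fell (4 adjusted over the list alone), with camera adjusted p = 0.0108 and adjusted p = 0.0786 with an estimated correlation. With major arms only the list was not called (0.512; range over its alternatives 0.000126 to 0.512). These were miR-92a-1-5p, miR-17-5p (0.78 ± 0.14, adjusted p = 0.00164, edgeR quasi-likelihood test), miR-25-5p (0.83 ± 0.22, adjusted p = 0.0204) and miR-92a-3p (0.48 ± 0.13, adjusted p = 0.0193). miR-92a-3p missed the threshold with total counts (0.32) and without either library of 0 h or 12 h (0.44 to 0.55). miR-25-3p and miR-93-5p had log2 changes of 0.07 ± 0.13 (-0.08 with total counts) and -0.15 ± 0.10. Over the trend 5 members rose (6 adjusted over the list alone), with adjusted p = 0.0158 and adjusted p = 0.155 with an estimated correlation. That call was also lost with major arms only (0.285) and at a mean of at least 10 CPM (0.0507; range 2.81e-05 to 0.285).

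The list of the miR-322 and miR-503 cluster, which promotes cell-cycle exit, was lower at 12 h at camera's preset correlation. It was not called with the correlation estimated from its members, which was 0.361. Of 11 measured members 3 fell and 0 rose (3 adjusted over the list alone), with camera adjusted p = 0.0103 and adjusted p = 0.537 with an estimated correlation. The list was also not called with major arms only (0.207) or at a mean of at least 10 CPM (0.108; range over its alternatives 0.00121 to 0.537). The 3 were miR-503-5p (not called without 12 h replicate 1, -1.28), miR-351-3p and miR-351-5p. miR-351-5p went from 9560 ± 1371 to 4623 ± 1064 CPM (SD, n = 2; log2 change -1.05 ± 0.19, adjusted p = 0.00165, edgeR quasi-likelihood test). miR-322-5p was at -0.39 ± 0.38 (adjusted p = 0.573, 0.0144 with the replicate block, range over its alternatives 0.0144 to 0.955) and miR-503-3p at -0.24 ± 0.20 (adjusted p = 0.486). Over the trend 4 members fell (4 adjusted over the list alone), with adjusted p = 0.0186 and adjusted p = 0.528 with an estimated correlation. It was not called there at a mean of at least 10 CPM or with major arms only (0.0941; range 0.00554 to 0.528).

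Of the miR-29 family 2 of 5 measured members rose at 12 h and 0 fell (3 rose adjusted over the list alone). miR-29a-3p went from 3493 ± 358 to 5510 ± 136 CPM (SD, n = 2; log2 change 0.66 ± 0.11, adjusted p = 0.00119, edgeR quasi-likelihood test), and miR-29b-1-5p rose as above. miR-29b-3p was at 0.51 ± 0.40 (adjusted p = 0.461). The list had a camera adjusted p = 0.0604 at 12 h and adjusted p = 0.497 with an estimated correlation. For the miR-29 family, miRNA list tests at 12 h against 0 h passed without 0 h replicate 2 (0.0230), either library of 1 h (0.0344 and 0.0384), 2 h replicate 1 (0.0491), 6 h replicate 2 (0.0475), either library of 10 h (0.0388 and 0.0390) or 12 h replicate 1 (0.0457; range over its alternatives 0.0157 to 0.512). Over the trend, where 2 members rose (3 adjusted over the list alone), it had adjusted p = 0.0303 and adjusted p = 0.303 with an estimated correlation. This call was lost at a mean of at least 10 CPM and with major arms only (0.139; range 0.000293 to 0.303).

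**Figure D3:**
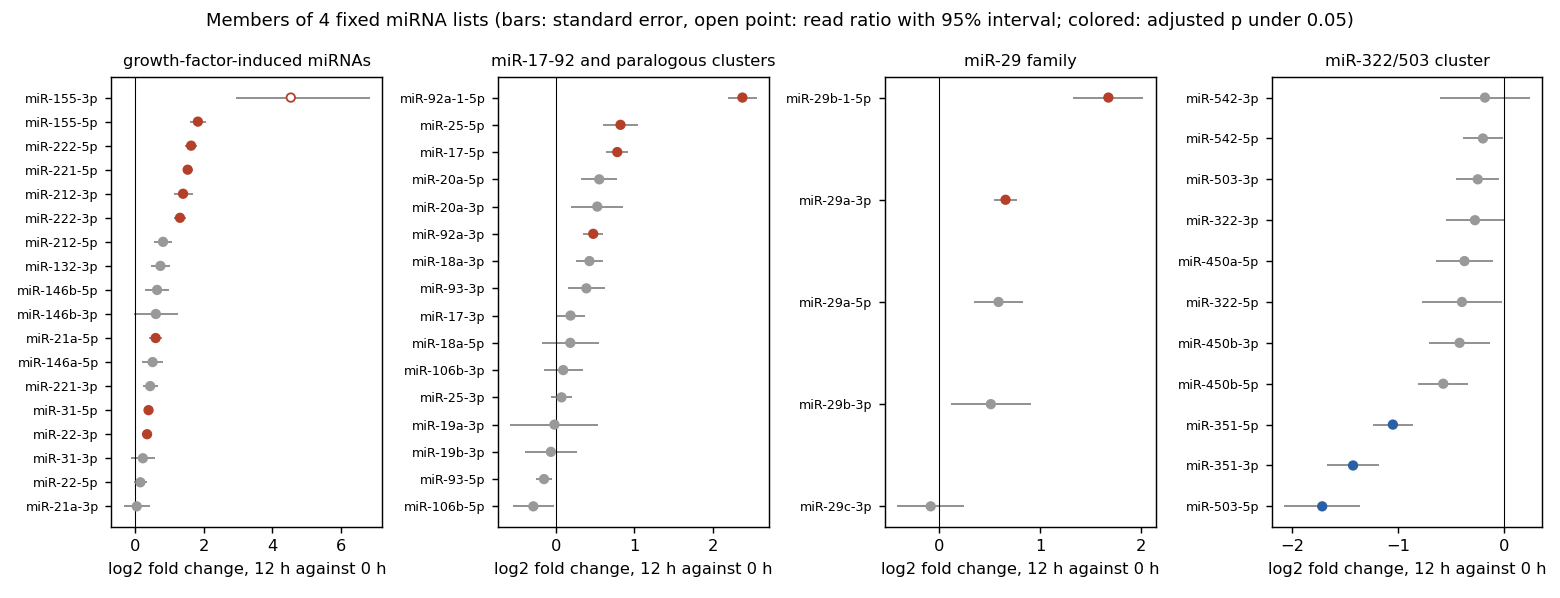
Log2 fold change at 12 h against 0 h (horizontal axes, points with SE bars) for the measured members of 4 lists, colored where the adjusted p was under 0.05 (red, higher; blue, lower; grey, not called). The growth-factor-induced list has 9 called members, all higher, and the cluster of miR-322 and miR-503 has 3, all lower. The open point is the read ratio of miR-155-3p, with 3 reads at 0 h, and its 95% interval. With total counts miR-22-3p, miR-21a-5p, miR-31-5p and miR-92a-3p are no longer called and miR-25-3p is at -0.08.

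The other lists were not called by camera at 12 h or over the trend. In the miR-30 family 2 of 12 measured members rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.589 at 12 h and 0.605 over the trend). miR-30c-5p fell, and miR-30b-5p fell by 1.30 (SE 0.22; adjusted p = 0.00119, edgeR quasi-likelihood test). miR-30c-2-3p rose by 0.77 ± 0.21 (adjusted p = 0.0274) and miR-30a-5p by 0.35 ± 0.11 (adjusted p = 0.0483). The call of miR-30a-5p was lost with total counts (0.19), without a low-count filter (0.37), with only the groups compared (0.33) and without either library of 0, 1, 8 or 12 h, 2 h replicate 1 or 4 h replicate 1 (0.33 to 0.43). In the let-7 family, which restrains proliferation, let-7i-5p rose (0.42 ± 0.10, adjusted p = 0.0102) and let-7b-5p fell (-0.69 ± 0.18, adjusted p = 0.0165) among 20 measured members (1 and 1 adjusted over the list alone; list adjusted p = 0.792 and 0.88). The call of let-7i-5p was lost with total counts (0.26) and without either library of 0 h or 12 h (0.43 to 0.46).

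Of 10 miR-15/16 members 0 passed at 12 h (0 adjusted over the list alone; list adjusted p = 0.677 and 0.612), and miR-16-5p was at -0.23 ± 0.09 (called with total counts, -0.39). Of 7 members of the p53-responsive miR-34 family 0 passed at 12 h (0 adjusted over the list alone; list adjusted p = 0.792 and 0.58). miR-34a-5p was at -0.76 ± 0.25 at 12 h (adjusted p = 0.0577, edgeR quasi-likelihood test, 0.00158 with the replicate block, range over its alternatives 0.000757 to 0.373) and fell by 0.0586 per hour over the trend (adjusted p = 0.00361). Among SRF-linked and muscle miRNAs 1 of 10 fell, miR-214-3p (-0.81 ± 0.12, adjusted p = 0.000295; 1 adjusted over the list alone; list adjusted p = 0.508 and 0.37), and with the replicate block miR-145a-5p passed too (0.0449; range over its alternatives 0.0449 to 0.504). In the miR-23/27/24 clusters miR-27a-5p rose (1.15 ± 0.30, adjusted p = 0.02) and miR-24-1-5p fell (-0.87 ± 0.24, adjusted p = 0.0278) among 14 (1 and 1 adjusted over the list alone; list adjusted p = 0.865 and 0.612), and with the replicate block miR-23b-3p passed too (0.0439; range over its alternatives 0.0439 to 0.587). Median, mean and test at 12 h differed in sign for the miR-34 family (0.06, -0.09, lower), the miR-30 family (0.03, -0.13, lower) and the miR-23/27/24 clusters (-0.001, 0.02, lower).

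Markers of other cells and loci were sparse. Of the 55 Dlk1-Dio3 hairpins 5 mature miRNAs were measured, and 0 passed at 12 h (0 adjusted over the list alone; list adjusted p = 0.444 and 0.169), while miR-411-5p and miR-410-3p rose over the trend. Of the blood markers 5 were measured and 0 changed at 12 h (0 adjusted over the list alone; list adjusted p = 0.677 and 0.58), while with the replicate block miR-486a-5p (0.00702) and miR-486b-3p (0.036) passed (ranges over their alternatives 0.00702 to 0.768 and 0.036 to 0.846). Of the liver and gut markers 3 were measured and 0 changed (0 adjusted over the list alone; list adjusted p = 0.865 and 0.638). Of 7 measured neural markers 1 rose at 12 h, miR-7a-5p (1.76 ± 0.37, adjusted p = 0.00439, edgeR quasi-likelihood test; 2 adjusted over the list alone; list adjusted p = 0.508 and 0.638). Over the trend miR-7a-5p also rose (0.157 per hour, adjusted p = 1.64e-05), and miR-128-3p and miR-9-5p fell. With the replicate block miR-219a-1-3p passed at 12 h too (0.0255; range over its alternatives 0.0093 to 0.393). Of the epithelial markers 2 were measured, too few for a list test. miR-203-3p rose at 12 h from 1.02 ± 0.657 to 3.86 ± 1.66 CPM (SD, n = 2; adjusted p = 0.0412; 1 adjusted over the list alone), and miR-205-5p was at -0.18 ± 0.28. The call of miR-203-3p was lost with total counts (1.73), with limma-voom (1.91) and without 0 h replicate 1 (1.39), 0 h replicate 2 (2.74) or 12 h replicate 2 (1.40). Of the 14 pluripotent cell hairpins 0 were measured.

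With an estimated correlation only the growth-factor-induced list was called, at 12 h and over the trend. With fry, which does not compare a list with other miRNAs, the miR-29 (0.0157), Dlk1-Dio3 (0.0386) and neural (0.0476) lists also passed at 12 h (ranges over their alternatives 0.0157 to 0.512, 0.0386 to 0.854 and 0.0476 to 0.901), and over the trend the Dlk1-Dio3 (0.00951) and SRF-linked and muscle (0.0243) lists did (ranges 0.00951 to 0.602 and 0.0243 to 0.665).

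The minor and major arms of 1 hairpin share their transcription. Both arms were measured for 142 hairpin names, where numbered copies at different loci were pooled under 1 name. At 12 h 16 minor arms rose and 10 fell, against 13 and 11 major arms. In 7 hairpins both arms were called. In 6 of them, miR-155, miR-222, miR-351, miR-455, miR-702 and miR-92a, both moved in 1 direction, and for miR-30c the minor arm miR-30c-2-3p rose while miR-30c-5p fell. miR-92a-3p and miR-30c-5p can come from more than 1 hairpin, so their partners are not fully matched. The same holds for other pairs, such as those of miR-129-5p, miR-29b-3p and miR-16-5p, which need not share 1 transcript. The median and share below include such pairs. The median log2 change of the minor arm minus that of the major arm was 0.055 (sign-flip permutation p = 0.302; -0.002 without 0 h replicate 1 and -0.019 without a low-count filter). Minor arms took 2.18 ± 0.0103% of reads at 0 h and 2.06 ± 0.118% at 12 h (SD, n = 2). Against hours over 16 libraries r was -0.218 (permutation p = 0.413) and rho was -0.172 (permutation p = 0.525). Shares of end classes were also correlated with hours, as given in the closing part. Without the 2 libraries farthest from the median time r was -0.041, within runs it was 0.0878 (permutation p = 0.846) and -0.395 (permutation p = 0.318), and without the 5 most abundant hairpins it was 0.384.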

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

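Apart from the random orders of the times, all tests in this part, the minimum of 200 CPM and the choice of end classes were chosen after the results were seen. For the end classes 6 classes were compared in 2 runs, and the adjusted values below are over these 12 tests, or over 12 more at a fixed mix of miRNAs. The tests of miR-21a-5p are not adjusted, and it was singled out of 112 miRNAs after its values were seen. Which of these changes come from time in serum and which from library preparation stays open, since no library was made in more than 1 way.

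Some early changes were smaller or no longer called at 12 h, where levels were tested against 2 h and 4 h (edgeR quasi-likelihood test, adjusted p in brackets). miR-155-3p was lower at 12 h than at 2 h by a log2 value of -2.53 ± 0.31 (0.00015) and than at 4 h by -1.20 ± 0.32 (0.0468). miR-181a-1-3p, which had fallen at 2 h and 4 h, was higher at 12 h by 0.82 ± 0.19 (0.0161) and 0.72 ± 0.19 (0.0468). miR-181b-1-3p was higher at 12 h than at 4 h by 1.41 ± 0.35 (0.0406).

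Reads with an added A at the 3' end (A-form) took a larger share late in the course, a class that no comparison above used. Their share was 2.07% at 0 h and 2.668% at 12 h in run 1 (r = 0.933 with hours, exact permutation p = 0.00055, adjusted 0.00171; rho = 0.857, exact p = 0.0107; r = 0.851 without the 2 farthest libraries), and 2.93% and 3.447% in run 2 (r = 0.747, exact p = 0.0309, adjusted 0.0412; rho = 0.738, exact p = 0.0458; r = 0.860). A change in which miRNAs are abundant is argued against, because at a fixed mix of miRNAs the share still rose by at least 0.546 points in each run (r = 0.957 and 0.978, exact p = 7e-05 and 0.00012, adjusted 0.00074 in both; rho = 0.976 and 1, exact p = 0.0004 and 5e-05, the smallest possible; r = 0.914 and 0.979 without the 2 farthest libraries). A few abundant miRNAs are argued against too, because 83 of 112 miRNAs rose in both runs and 13 fell in both. Added A may follow time in serum, as a hypothesis, and a drift in library preparation along the time order was not tested.

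The share of C-form reads of miR-21a-5p rose from 2.37% (95% Wilson interval 2.32 to 2.42) to 6.96% (6.89 to 7.03) in run 1 and from 2.48% (2.43 to 2.52) to 9.169% (9.10 to 9.24) in run 2. With hours r was 0.907 in both runs (exact permutation p = 0.00206 and 0.00387), rho was 1 (exact p = 4.96e-05, the smallest that 40320 orders can give) and 0.881 (exact p = 0.00724), and r without the 2 farthest libraries was 0.896 and 0.916. C added to all miRNAs by like amounts is argued against, because the median change of the other 111 miRNAs was at most 0.0212 points, although miR-30a-3p gained 1.92 and 2.74 points. Their shares were small, so a change in points cannot exclude a proportional rise. Pooled over these 111, the share went from 0.567% to 0.702% in run 1 and from 0.0904% to 0.104% in run 2. These rises were smaller in proportion than that of miR-21a-5p. A fixed share of templated ends read as C-form is argued against, because C-form reads per templated-extension read rose at least 2.205 times. The next templated base is C, so a shift among templated ends that are counted as C-form stays open. A change in the end processing of miR-21a-5p may underlie this, as a hypothesis; C-form shares of some miRNAs differed between runs (miR-125b-5p 8.20% and 0.942%), so a technical source stays open.

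The other end classes that were compared, also outside the comparisons above, moved as follows in run 1 and run 2. The G and mixed forms and the 5' extended reads were not compared. All non-templated 3' reads together took 10.5% and 10.6% at 0 h and 11.6% and 11.6% at 12 h. C-form reads took 0.678% and 0.253% at 0 h and 1.19% and 0.967% at 12 h (r = 0.955 and 0.953, exact p = 0.00045 and 0.00057, adjusted 0.00171 in both; rho = 0.976 and 0.929, exact p = 0.0004 and 0.00223; r = 0.9496 and 0.902 without the 2 farthest libraries). Most of this rise came from miR-21a-5p, whose C-form reads went from 0.143% to 0.539% of all reads in run 1 and from 0.166% to 0.868% in run 2. Of 112 miRNAs 46 rose and 10 fell in both runs, with median changes of 0.0214 and 0.0009 points. Reads extended with templated bases took 8.62% and 8.84% at 0 h and 10.209% and 11.116% at 12 h (r = 0.975 and 0.756, exact p = 0.00025 and 0.0176, adjusted 0.00171 and 0.0264; rho = 0.976 and 0.714, exact p = 0.0004 and 0.0576; r = 0.987 and 0.568). This was not general, since 48 miRNAs rose and 43 fell in both runs (median changes 0.0080 and -0.0042 points), and miR-21a-5p gained 12.3 and 11.8 points. Most of the rise came from miR-21a-5p, whose templated reads went from 2.13% to 3.64% of all reads in run 1 and from 2.44% to 4.52% in run 2. The values at a fixed mix below still include miR-21a-5p, so for C-form and templated reads they do not show a general rise. U-form reads fell from 5.11% and 4.73% to 4.64% and 4.06% (r = -0.812 and -0.866, exact p = 0.0111 and 0.00742, adjusted 0.0190 and 0.0148; rho = -0.595 and -0.881, exact p = 0.132 and 0.00724; r = -0.901 and -0.824), while 36 miRNAs rose and 41 fell in both runs (median changes -0.0030 and 0 points). Exact reads had r = -0.934 and -0.529 (exact p = 0.00151 and 0.177, adjusted 0.00363 and 0.193; rho = -0.810 and -0.381, exact p = 0.0218 and 0.360; r = -0.903 and -0.0149), and 28 miRNAs rose and 74 fell in both runs. Trimmed reads had r = -0.218 and -0.664 (exact p = 0.608 and 0.0781, adjusted 0.608 and 0.0937; rho = -0.405 and -0.571, exact p = 0.327 and 0.151; r = -0.142 and -0.777), and 50 miRNAs rose and 48 fell in both runs. At a fixed mix of miRNAs the sign for trimmed reads was the opposite, with shares of 25.7% and 25.4% at 0 h and 26.3% and 26.3% at 12 h (r = 0.672 and 0.519, exact p = 0.0706 and 0.187, adjusted 0.0770 and 0.187; rho = 0.405 and 0.452, exact p = 0.327 and 0.267; r = 0.901 and 0.228 without the 2 farthest libraries). Exact reads at a fixed mix had r = -0.965 and -0.964 (exact p = 0.00025 and 0.00047, adjusted 0.00099 and 0.00113; rho = -0.929 and -0.976, exact p = 0.00223 and 0.0004; r = -0.995 and -0.929). At a fixed mix r was 0.913 and 0.911 for C-form reads (exact p = 0.00193 and 0.0034, adjusted 0.00387 and 0.00453; rho = 0.976 and 0.881, exact p = 0.0004 and 0.00724; r = 0.883 and 0.918) and 0.966 and 0.919 for templated ones (exact p = 0.00035 and 0.00265, adjusted 0.00104 and 0.00398; rho = 0.976 and 0.929, exact p = 0.0004 and 0.00223; r = 0.973 and 0.887). For U-form reads it was -0.830 and -0.898 (exact p = 0.00942 and 0.00246, adjusted 0.0113 and 0.00398; rho = -0.619 and -0.857, exact p = 0.115 and 0.0107; r = -0.815 and -0.804).

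The 113 trend calls were set against random orders of the times within each run. Of 100 orders, the real one included, 1 gave as many calls, and the highest other order gave 43. A random order of the times is argued against, though 1 in 100 is the smallest share that this number of orders can give. The test cannot tell time in serum from a drift in library preparation along the time order.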

How the results depend on the processing

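The setting that leaves out 10 h replicate 2 and 2 h replicate 2 was chosen after seeing the data. The cause was not tested for any change listed here, except that fewer libraries or fewer miRNAs entered where the setting says so. Single libraries were left out for counts, lists and the miRNAs named by the rule, of which 46 values passed the threshold, 21 without every single library and 25 not without at least 1. Depth limits miRNAs of 1 to 3 reads, for which ratios of reads are given at single times.

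With the replicate block the counts were 110 for any change, 5, 31, 66, 77, 81, 84 and 108 at 1 to 12 h, and the block changed no call among the named miRNAs other than those given beside the results. At a mean of at least 10 CPM they were 39 for any change and 0, 7, 15 and 20 at 1, 2, 4 and 6 h. Without a filter they were 101 for any change and 20 at 2 h, where DESeq2 gave 18, a fit of only the groups compared 5, and the fit without 10 h replicate 2 and 2 h replicate 2 also 5; the latter gave 45 at 8 h and 30 at 10 h. Without the 0 h libraries 59 trends passed. Called lists numbered 1 with an estimated correlation, 6 with fry and 1 with major arms only at 12 h, and 1, for the trend, with an estimated correlation, major arms only or a mean of at least 10 CPM. Without single libraries the counts lay between 36 and 60 for any change, 0 and 3 at 1 h, 2 and 13 at 2 h, 14 and 36 at 4 h, 16 and 38 at 6 h, 20 and 43 at 8 h, 23 and 60 at 10 h, 37 and 65 at 12 h and 96 and 120 for the trend.

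Of the named miRNAs' values 21 changed sign under some setting, none of them past the threshold (0 in either fit), and the largest was 0.561 in size. With total counts these were miR-99b-5p (-0.0245), miR-27b-3p (-0.0776), miR-25-3p, 12 h against 0 h (-0.0829), let-7a-5p, 12 h against 0 h (-0.0651), miR-34c-5p (-0.0989), miR-27a-3p (-0.0583), miR-30d-5p (-0.152), miR-127-3p (-0.0852), miR-192-5p (-0.0206) and miR-138-5p (-0.138). At a mean of at least 10 CPM they were miR-15b-3p (0.0114) and miR-194-5p (0.0128), without 10 h replicate 2 and 2 h replicate 2 the same miRNAs (0.00363 and 0.00474), with only the groups compared miR-30d-5p, 12 h against 0 h (-0.00449) and miR-138-5p, 12 h against 0 h (-0.00191), and with limma-voom miR-127-3p (-0.021). Lists that changed direction, none called, were let-7 at 12 h (adjusted p = 0.975 at a mean of at least 10 CPM; range 0.529 to 0.975), miR-23/27/24 at 12 h (0.935 with the replicate block, 0.869 at a mean of at least 10 CPM; range 0.825 to 0.975), let-7 over the trend (0.985 with major arms only, 0.989 with total counts, 0.871 at a mean of at least 10 CPM; range 0.572 to 0.989) and neural markers over the trend (0.789 with major arms only; range 0.145 to 0.874). The arm difference was -0.019 without a filter, and the arm share's r 0.384 without the 5 most abundant hairpins.

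Without single libraries the ranges of values that changed sign were -0.215 to 0.0758 for let-7c-1-3p, -0.567 to 0.0287 for miR-322-3p, -0.254 to 0.0505 for miR-15b-5p, 12 h against 0 h, -0.0702 to 0.0547 for miR-15b-3p, -0.257 to 0.123 for miR-29c-3p, -0.0651 to 0.227 for miR-34c-5p, 12 h against 0 h, -0.381 to 0.130 for miR-34b-3p, -0.0229 to 0.948 for miR-449a-5p, -0.0828 to 0.137 for miR-30d-5p, 12 h against 0 h, -0.561 to 0.559 for miR-127-3p, -0.812 to 0.307 for miR-205-5p, -0.163 to 0.995 for miR-486a-3p, -0.0611 to 0.0473 for miR-194-5p, 12 h against 0 h, -0.297 to 0.560 for miR-215-5p, -0.184 to 0.247 for miR-138-5p and -0.00198 to 0.101 for the arm difference. Adjusted p ranged from 0.357 to 0.940 for blood markers and 0.583 to 0.940 for liver and gut markers at 12 h, and from 0.572 to 0.985 for let-7 over the trend.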

Other observations

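The miRNAs and the tests in this part were chosen after their values were seen. miR-125b-1-3p, the passenger arm of a hairpin of the abundant miR-125b, rose at 12 h from 799 ± 93.0 to 2666 ± 70.9 CPM (SD, n = 2; log2 change 1.74 ± 0.15, adjusted p = 2.76e-06, edgeR quasi-likelihood test). miR-129-5p rose by 1.28 ± 0.28 (adjusted p = 0.00669), miR-5099 by 1.36 ± 0.26 (adjusted p = 0.00267) and miR-365-2-5p by 1.40 ± 0.33 (adjusted p = 0.0102). The more abundant arm paired with miR-129-5p, miR-129-2-3p, had a log2 change of -1.53 and was not called. miR-467d-3p fell by 1.23 (SE 0.26; adjusted p = 0.00439) and miR-467a-5p by 0.93 (SE 0.19; adjusted p = 0.00365), members of the large repeated family to which miR-466h-3p belongs. miR-193a-3p fell by 1.07 (SE 0.31; adjusted p = 0.0316) and the Hox cluster miRNA miR-196b-5p by 0.86 (SE 0.20; adjusted p = 0.00813). Single libraries were not left out for these miRNAs.

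miR-210-5p moved down and up. It was at 19.1 ± 3.85 CPM (SD, n = 2) at 0 h, 9.87 ± 0.0828 at 2 h, 28.2 ± 0.941 at 4 h, 33.4 ± 2.99 at 6 h and 10.5 ± 2.12 at 12 h (adjusted p = 8.98e-05 for any change, edgeR quasi-likelihood test). Its other arm, miR-210-3p, was at 147.8 ± 30.9 CPM at 0 h and 152 ± 7.45 at 12 h (adjusted p = 0.978 for any change). The difference between the arms was not tested. The 12 h fall of miR-210-5p by 0.86 (SE 0.23; adjusted p = 0.02) was lost without 0 h replicate 1 (-0.61) or 12 h replicate 2 (-0.64).

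Across 112 miRNAs, which are not independent replicates, the trimmed share tended to move against abundance over 12 h. The trimmed share changed by -15.4 and -15.8 points in the 2 runs for miR-155-5p and by -17.2 and -17.8 for miR-29a-3p, against 12.1 and 16.4 for miR-335-3p and 8.55 and 8.41 for miR-214-3p. Not all miRNAs followed this, since miR-30c-5p (-1.44 and -2.15) and miR-30b-5p (-0.814 and -0.953) fell in abundance and lost trimmed reads. Shared counting noise is argued against, because with abundance from 1 run and trimming from the other rho was -0.503 (permutation p = 1e-05, the smallest possible; adjusted 2e-05) and -0.339 (permutation p = 0.00036; adjusted 0.00048, over 8 such correlations). Over 55 miRNAs whose own names carry no letter, rho was -0.522 and -0.376 (permutation p = 9e-05 and 0.00513, adjusted 0.000144 and 0.00513). This set still holds miRNAs with close relatives, such as miR-98-5p of the let-7 family. It therefore cannot decide whether reads shared between paralogs play a part. Without the 10 most abundant miRNAs rho was -0.530 and -0.347 (permutation p = 1e-05, the smallest possible, and 0.00044). The 2 other correlations were over miRNAs chosen by their abundance trend and add no independent support. Newly made miRNAs may be less trimmed than old ones, a hypothesis that these libraries leave untested, since the age of molecules was not measured.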
